A study of Homo sapiens with 6 samples.

How the data were processed

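RNA from MCF-7 cells, an established human breast adenocarcinoma line that carries the estrogen receptor, was measured on 6 short-oligonucleotide arrays whose probe set names follow the Affymetrix scheme. The array titles name a CYT fraction for 3 arrays and a MEM fraction for 3. These were read as RNA of free polysomes, which translate in the cytosol, and RNA of polysomes bound to membranes. Replicates were numbered 1 to 3 in each fraction. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. They also do not say how the fractions were separated or whether equal amounts of RNA were labelled.

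The authors deposited a table of log2 values with 22283 probe sets and a column per array. The log base was taken from the range of the values, which spanned 3.05 to 13.91 and would exceed what an array scanner records in any larger base. The method that turned probe intensities into these log2 values, its background correction and its centring are not given in the sources used here. The columns had medians between 6.97 and 7.04, so the arrays had been brought to a similar level before deposit. This scale shows how abundant an mRNA was relative to the other mRNAs on the same array, not its number of copies per fraction. For arrays, their number limits the precision: 3 per group gave a median standard error (SE) of 0.0986 for a log2 difference.

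Probe sets were named from the platform annotation, with symbols looked up by gene identifier in a RefSeq table of assembly GRCh38.p14. Of the 22215 probe sets that were not manufacturer controls, 19065 had 1 gene, 1043 had several and 2107 had none. The identifiers of 19053 were found in the RefSeq table and 0 symbols changed. Genes were not named from probe sets with several. No genome build is named in the deposited table, so no coordinates are given. Where a gene had several probe sets, the set with the highest mean over the 6 arrays stood for it, which gave 11963 genes. Of the 4310 genes with several probe sets, 23 had sets past the threshold in opposite directions. Probe sets ending in _s_at or _x_at can share sequence with paralogs, pseudogenes or other transcripts, so values of ribosomal proteins, tubulins, HSP90 genes, GAPDH and class I histocompatibility genes are uncertain in that respect.

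The 68 control probe sets were left out, and no filter on dim probe sets was used. Differences were computed as membrane-bound minus free with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 4 residual degrees of freedom, and p-values were adjusted over 22215 probe sets by the Benjamini-Hochberg method. A probe set passed at an adjusted p under 0.05. An exact permutation of 3 arrays against 3 cannot give a p under 0.1, so p-values rest on limma's model, which pools variance across probe sets. The planned test added a pseudocount to linear values. The deposited values were already on a log scale, so none was added.

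Before the data were examined, 36 gene lists were fixed, together with 5 comparisons between pairs of lists, the alternatives and the rule for named genes. Lists were tested with camera of limma, which asks whether a list shifted relative to the other genes, with a preset correlation between genes of 0.01, and also with a correlation estimated from the data. Lists needed at least 5 members, which left 35. Adjusted p-values of lists were adjusted over those 35, and those of pairs over the 5 pairs. The named genes were the 12 with the largest positive and the 12 with the largest negative log2 difference among genes whose 3 values in each group did not overlap and whose higher mean lay above the median of all probe sets, the 2 highest and 2 lowest members of each list, and 24 benchmark genes. The plan also took in any gene that changed sign under an alternative, but sign changes were followed only among genes named otherwise. Other genes named in the text were chosen after their values were seen.

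The fit was tested on simulated data with 3 and 3 arrays and 22215 probe sets, of which 50 each were changed by 0.25, 0.5, 1 and 2 log2 units. It recovered 0%, 56%, 100% and 100% of them, and 6.57% of its 137 calls were false. Of 40 unchanged lists, 0 were called. The simulation changed 200 probe sets, whereas 47.3% were called in the data, so its recovery and false call rates need not hold there. Its values were drawn independently, while members of real lists can vary together. The 0 of 40 therefore says nothing about the preset correlation.

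Alternatives covered pseudocounts of 1 and 64, leaving out the dimmest 40% or 60% of probe sets, quantile normalization, median centring, quantile normalization within groups and centring on lists of soluble proteins. They also covered limma's intensity trend with and without robust estimation, a block for the replicate number, leaving out each array, a test against a 1.2-fold margin, averaging probe sets and leaving out probe sets ending in _s_at or _x_at. Camera was not run with the margin or robust estimation, nor were the pair tests with those or with fry. A planned check of transcript length and GC content was not run, because no transcript sequences were at hand. Plots were drawn with matplotlib 3.10.9.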

Results

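Free and membrane-bound polysomes of MCF-7 cells were compared on 6 arrays, 3 of each fraction, to ask which mRNAs were translated at membranes and which in the cytosol. Arrays of the same fraction correlated with Pearson's r of 0.993 to 0.997 across probe sets, and arrays of different fractions with 0.936 to 0.941. These correlations are across probe sets, which are not independent replicates. The first principal component held 90.6% of the variance and separated the fractions. The second held 4.84% and set free replicate 1 and membrane-bound replicate 3 apart from the other 4 arrays. Those 2 arrays also had a wider spread of values, with an SD over probe sets of 1.98 and 1.99 against 1.90 to 1.94 on the others.

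Genes of lysosomal proteins and of the machinery that imports and folds proteins in the endoplasmic reticulum (ER) mostly rose in membrane-bound polysomes. Their lists passed camera against all other genes with a preset correlation, but 0 of 35 lists passed with an estimated correlation, where the lowest adjusted p was 0.0546. The mRNA of PTPRO, a receptor-type tyrosine phosphatase, rose 19.6-fold on the brighter of its 2 probe sets. Its log2 value there was 6.37 ± 0.011 in free and 10.66 ± 0.093 in membrane-bound polysomes (SD, n = 3 each), a difference of 4.29. The mean of the 2 probe sets rose by only 2.17 log2 units, so the other probe set showed little of this rise. ER chaperones and folding enzymes had a median difference of 1.94 log2 units, and 38 of 39 rose. Splicing factors, proteasome subunits and cytosolic chaperones lay lower in the membrane-bound fraction, with medians between -0.64 and -0.72. Those 3 lists and the replication list also served to centre the arrays in an alternative, which puts their medians near 0 by construction.

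Of 22215 probe sets, 10501 passed limma's test at an adjusted p under 0.05, or 47.3%. They comprised 3344 that were higher in the membrane-bound fraction and 7157 that were lower. The sizes were unequal. At least 2-fold differences were found for 1937 probe sets, of which 1814 were higher and the rest lower, and at least 4-fold differences for 671 higher and 0 lower. On 1 probe set per gene, 1952 genes were higher and 4248 lower out of 11963, of which 1087 and 48 differed at least 2-fold. The 3 values of each group did not overlap for 57.7% of genes, against 10% by chance. Of the probe sets called on the deposited scale 31.8% were higher. With each array centred on the proteasome, cytosolic chaperone, splicing and replication lists, 16888 were higher and 245 lower, because the median of all genes moved up by 0.67 log2 units. "Lower" therefore means lower relative to the other mRNAs on the array as deposited. Of the 21 lists with a median below 0 as deposited, 20 had more members called higher than lower with that centring, and the cytosolic chaperones had 4 higher and 5 lower. Of the decreases named below, those of ESR1, CCND1, SRP54, SLC25A36, TUBB3, UBE2J1, ALG13, ACAT2, ASNS, CEBPG, EIF4H, ETF1, WARS1, MRPL49, RPE, RAB31, VPS37C, H4C8, RPL39L and NUP62 stayed below 0 but did not pass with that centring, at -0.26 to -0.01. The few probe sets at least 2-fold lower depended on single arrays, with 279 without membrane-bound replicate 3 and 66 without membrane-bound replicate 1, and numbered 234 on the 4 arrays left without free replicate 1 and membrane-bound replicate 3.

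After PTPRO, the largest increases belonged to PCYOX1, a lysosomal prenylcysteine oxidase (3.54 ± 0.17 log2 units, SE, n = 3 per group), GJA1, the gap junction protein connexin 43 (3.50 ± 0.14), NUCB2, the secreted precursor of nesfatin (3.43 ± 0.15), and HSPA13, a chaperone of microsomes (3.21 ± 0.17). OSTM1 and LAMP2, both lysosomal membrane proteins, rose by 3.15 and 3.09, and GGH, a lysosomal and secreted hydrolase, by 3.00. DSG2, a desmosomal cadherin, rose by 3.10, CD58, a surface adhesion ligand, by 3.02 (1.47 without probe sets ending in _s_at or _x_at), SERINC1, a multipass membrane protein, by 2.99 and ADAM9, a membrane-anchored protease, by 2.97. The largest decreases under the rule for named genes were smaller. Over all probe sets the largest was -1.55, on a probe set outside that rule. DUSP4, a nuclear phosphatase of MAP kinases, fell by 1.24 ± 0.12, which is 2.36-fold, and TPM4, a tropomyosin of the actin cytoskeleton, by 1.22 ± 0.095. UBE2G2, a ubiquitin-conjugating enzyme of ER-associated degradation that lacks a membrane anchor, fell by 1.21 and POLR2E, an RNA polymerase subunit, by 1.18, and DCAF7, a WD-repeat scaffold protein, was 2.30-fold lower. HNRNPF and HNRNPM, which bind nuclear pre-mRNA, fell by 1.14 and 1.09 (HNRNPM by a log2 difference of -0.08, adjusted p 0.545, without probe sets ending in _s_at or _x_at), MCM4 of the replicative helicase by 1.14 and LMNB2, a lamin, by 1.14. SH3BGRL3, CETN3 and PDAP1 fell by 1.11, 1.10 and 1.10, and PDAP1 stood at -0.61 on the mean of its probe sets. With a pseudocount of 64, PCYOX1, GJA1 and OSTM1 stood at 2.10, 1.85 and 2.09. Centred on the soluble-protein lists, DUSP4 was still lower by a log2 difference of -0.56 and TPM4 by -0.55. Adjusted p-values of these 24 genes from limma were 3.39e-05 (CETN3) or less.

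**Figure D1:**
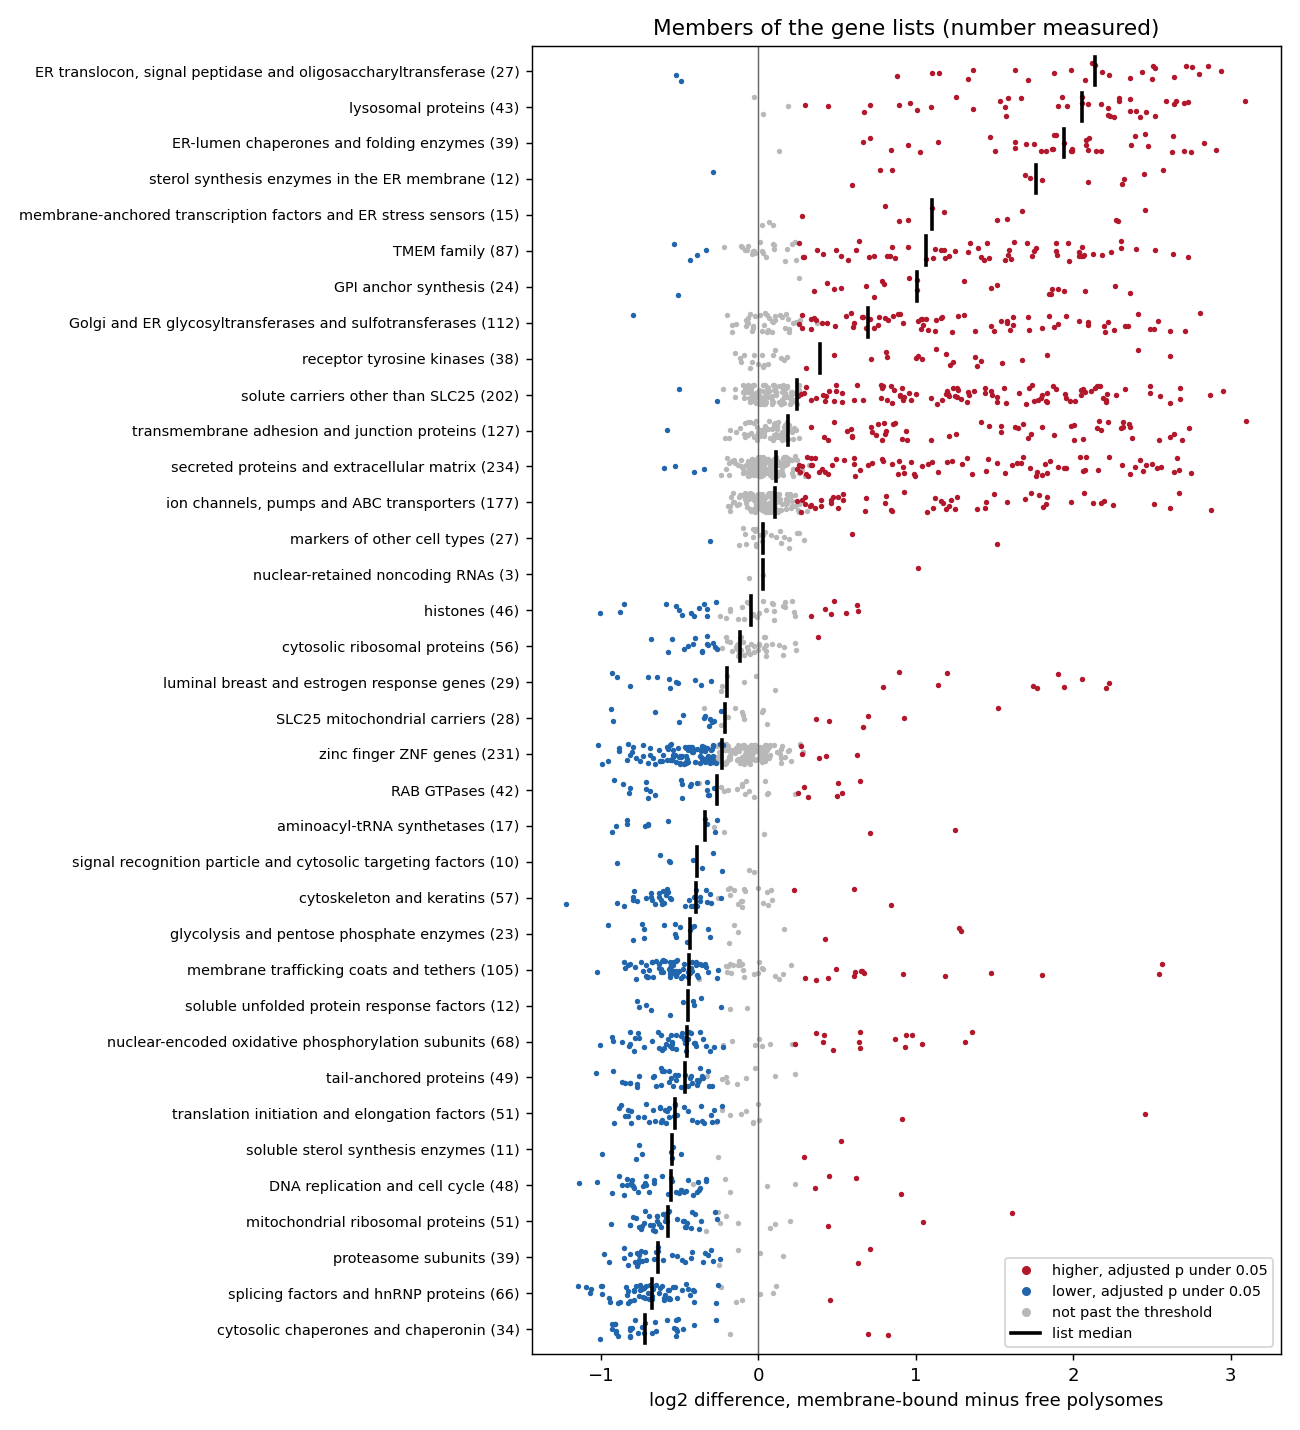
Log2 difference between membrane-bound and free polysomes (horizontal axis) for the measured members of 36 gene lists, with 1 point per gene, the number of members in parentheses and a black bar at each list median; red and blue points passed limma's test at an adjusted p under 0.05 and grey points did not. The ER folding, lysosomal and translocon lists have medians of 1.94 to 2.14, secreted and matrix proteins 0.12 (1.64 without the dimmest 60% of probe sets) and cytosolic chaperones -0.72, and 19 of the 21 medians below 0 move above 0 when arrays are centred on soluble-protein lists.

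The ER folding machinery rose almost as a whole. PPIB, a prolyl isomerase of the ER lumen, rose by 2.91 ± 0.094 and RCN2, a calcium-binding protein there, by 2.83. Among the benchmarks, HSP90B1 (GRP94) rose by 2.48, HSPA5 (BiP) by 1.99, P4HB (protein disulfide isomerase) by 1.87 and CALR (calreticulin) by 0.67, or by 2.73 on a probe set without an _s_at or _x_at ending. FKBP10 had the lowest difference, 0.13 ± 0.13 (adjusted p 0.455). Its probe set was dim, at 6.32 in free and 6.45 in membrane-bound polysomes, below the median of all probe sets (7.05). In the translocon, signal peptidase and oligosaccharyltransferase list 25 of 27 genes rose, with a median of 2.14. Its highest member was SSR3 of the translocon-associated complex at 2.94, followed by KTN1, the kinectin membrane anchor, at 2.86, and SEC61A1, the channel subunit, rose by 2.50. The 2 members that fell were SERP1 (-0.52) and SEC61B (-0.49), both small proteins anchored by a C-terminal tail; centred on the soluble-protein lists they stood at 0.15 and 0.18. Adjusted over the list alone, 38 and 25 genes rose in the 2 lists. Camera gave an adjusted p of 6.55e-28 for the folding list, and adjusted p = 0.0546 with an estimated correlation. For the translocon list these were 5.71e-19, and adjusted p = 0.0758 with an estimated correlation.

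Lysosomal proteins rose in 40 of 43 cases (40 adjusted over the list alone), with a median of 2.05. NPC1, the cholesterol transporter of late endosomes, rose by 2.73 (1.42 on the mean of its probe sets). The probe set of the protease CTSZ differed by 0.03 (adjusted p 0.854), though the mean of its probe sets passed at 0.28 (adjusted p 0.0119), and that of IDS, a sulfatase, by -0.03 (adjusted p 0.846), which was 0.65 after centring on soluble-protein lists. The CTSZ probe set was dim, at 6.12 in free and 6.15 in membrane-bound polysomes. Glycosyltransferases and sulfotransferases of the Golgi and ER rose in 73 of 112 cases and fell in 1 (75 and 1 adjusted over the list alone), with a median of 0.70, and 53 of 56 rose without the dimmest 60% of probe sets. In a cut made after the results were seen, at the same percentage of the free arrays alone, 37 of 42 rose and 1 fell. MAN2A1, a Golgi mannosidase, rose by 2.80 and GALNT7, which starts O-glycans, by 2.71; ALG13, the cytosolic catalytic subunit of a glycosyltransferase held at the ER by its partner, fell by 0.79 (-0.37 without probe sets ending in _s_at or _x_at). Of 24 genes of GPI anchor synthesis 22 rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 1.01. PIGK and PIGT, subunits of the GPI transamidase, rose by 2.36 (1.55 with a pseudocount of 64) and 2.27, and PIGA had a difference of -0.51, which became 0.16 after centring on the soluble-protein lists and did not pass without free replicate 1 (-0.25), membrane-bound replicate 1 (-0.44) or membrane-bound replicate 2 (-0.50). In camera the adjusted p was 5.92e-27 for lysosomal proteins, 3.92e-20 for glycosyltransferases and 2.49e-13 for GPI synthesis. With an estimated correlation, these were adjusted p = 0.0758, 0.0546 and 0.0758.

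Almost all plasma membrane proteins that passed had risen, and those that did not pass were often dim. Shares among brighter members are given with the dimmest 60% of probe sets left out, and in a cut made after the results were seen, at the same percentage of the free arrays alone, since the level over all 6 arrays includes the rise itself. Of 38 receptor tyrosine kinases 20 rose and 0 fell (20 and 0 adjusted over the list alone); 16 of 19 rose without the dimmest probe sets and 11 of 14 in the free cut. ERBB3 rose by 2.61 ± 0.093, EPHA4 by 2.41 and ERBB2, the HER2 receptor, by 1.68. The ERBB3 value rested on a probe set ending in _s_at; without such sets another probe set gave -0.12 (adjusted p 0.383), and the mean of its probe sets was 1.24. Adhesion and junction proteins rose in 55 of 127 cases and fell in 1 (55 and 1 adjusted over the list alone); 35 of 39 rose without the dimmest and 28 of 32 in the free cut. DSG2 and OCLN (occludin, 2.74) led them, CDH1 (E-cadherin) rose by 2.00 and EPCAM by 1.54, and ITGAE fell by 0.58, a value of 0.091 after centring on soluble-protein lists. Camera gave adjusted p-values of 4.28e-08 for the kinases and 3.41e-14 for adhesion proteins; adjusted p = 0.15 and 0.104 with an estimated correlation.

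Transporter families differed. Solute carriers other than the SLC25 family rose in 98 of 202 cases and fell in 2 (99 and 2 adjusted over the list alone); 74 of 80 rose without the dimmest 60% of probe sets, with a median of 1.44, and 48 of 58 in the free cut. SLC27A2, a fatty acid transporter, rose by 2.95, SLC39A14, a zinc transporter, by 2.87 and SLC7A5, an amino acid transporter, by 2.21. The SLC25 family, taken by name, holds mostly carriers of the inner mitochondrial membrane and also SLC25A17 of peroxisomes. It rose in 6 and fell in 12 of 28 cases (6 and 13 adjusted over the list alone). With centring on soluble-protein lists 22 rose and 1 fell. SLC25A36 and SLC25A1 fell by 0.93 and 0.92, and SLC25A32 and SLC25A20 rose by 1.52 and 0.93. The medians of the 2 families, 0.25 and -0.21, differed by 0.46, and by 1.18 and 1.73 without the dimmest 40% and 60% of probe sets (camera between the lists, adjusted p 1.81e-08; adjusted p = 0.0149 with an estimated correlation). Ion channels, pumps and ABC transporters rose in 55 and fell in 0 of 177 cases (53 and 0 adjusted over the list alone; 29 of 33 rose without the dimmest 60% and 23 of 27 in the free cut), led by ABCA12 (2.87, or 1.90 with a pseudocount of 64) and ABCC4 (2.67). Genes named TMEM rose in 61 of 87 cases and fell in 4 (61 and 4 adjusted over the list alone), with a median of 1.06; TMEM30A rose by 2.73 and TMEM38B by 2.64, whereas TMEM243 and TMEM11, the latter a mitochondrial protein, fell by 0.53 and 0.43, which became 0.14 and 0.24 after centring on soluble-protein lists. By camera the adjusted p was 2.22e-18 for solute carriers, 0.702 for SLC25, 8.94e-09 for channels and 7.07e-20 for TMEM genes. With an estimated correlation, these were adjusted p = 0.0758, 0.756, 0.286 and 0.0546.

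Secreted and extracellular matrix proteins rose in 80 of 234 cases and fell in 4 (77 and 4 adjusted over the list alone); 48 of 58 rose without the dimmest 60% of probe sets and 37 of 47 in the free cut. CPD, a carboxypeptidase that spans the membrane, rose by 2.74 and SCUBE2, a secreted signalling protein, by 2.67. The 4 that fell were FGF13 (-0.60) and FGF12 (-0.34), fibroblast growth factor homologs that stay inside the cell, SERPINB5 (-0.53), of the serpin clade that is mostly intracellular, and LTBP4 (-0.41), a matrix protein; After centring on soluble-protein lists FGF13, SERPINB5, FGF12 and LTBP4 stood at 0.071, 0.15, 0.33 and 0.27, and SERPINB5 at -0.35 with a pseudocount of 64. FGF12 and LTBP4 were chosen after their values were seen. Camera gave an adjusted p of 1.28e-10, and adjusted p = 0.286 with an estimated correlation. Markers of other cell types rose in 2 of 27 cases and fell in 1 (2 and 0 adjusted over the list alone), with an adjusted p of 0.0832 (adjusted p = 0.607 with an estimated correlation). The 2 were COL3A1 (1.52, but 0.061 with an adjusted p of 0.707 without probe sets ending in _s_at or _x_at), a fibrillar collagen, and TAGLN (0.59, or 0.32 with a pseudocount of 64), a smooth muscle actin-binding protein, and KRT14, a basal keratin, had a difference of -0.30, or 0.37 after centring on soluble-protein lists, that did not pass without free replicate 2 (-0.29), free replicate 3 (-0.21) or any of membrane-bound replicates 1, 2 and 3 (-0.32, -0.29 and -0.29). Without membrane-bound replicate 3, 6 of these markers rose and the adjusted p was 0.0165 (6 and 0.0428 without free replicate 1 as well), within a range of 0.0165 to 0.487 over the alternatives.

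Sterol synthesis divided between the fractions. The list of its enzymes in the ER membrane was defined with INSIG1, INSIG2, SCAP and LDLR, which are not synthesis enzymes, beside them. Of its 12 measured members 11 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 1.76. SC5D rose by 2.57 (0.43 without probe sets ending in _s_at or _x_at) and MSMO1 by 2.45. LSS, which holds to the membrane without spanning it, had a difference of -0.28, or 0.39 after centring on soluble-protein lists, that did not pass without free replicate 2 (-0.29), free replicate 3 (-0.29), membrane-bound replicate 1 (-0.27) or membrane-bound replicate 2 (-0.21). The list of 11 soluble enzymes held ACACA, ACLY and FASN of fatty acid synthesis beside those of sterol synthesis, and 8 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.55 that became 0.12 with that centring and -0.21 without probe sets ending in _s_at or _x_at. IDI1, an isomerase of sterol synthesis, fell by 0.99 and ACAT2 by 0.78. The 2 that rose were ACACA, acetyl-CoA carboxylase, by 0.53 (0.30 on the mean of its probe sets) and MVK, mevalonate kinase, by 0.29, the latter not past the threshold without membrane-bound replicate 1 (0.25) or membrane-bound replicate 2 (0.29). The 2 lists differed by 2.31 log2 units in their medians (adjusted p 6.1e-07; adjusted p = 0.0149 with an estimated correlation). Against all other genes, camera gave adjusted p-values of 4.5e-09 and 0.0481 (adjusted p = 0.121 and 0.305 with an estimated correlation). The soluble list did not pass without free replicate 1 (adjusted p 0.0543) or membrane-bound replicate 1 (0.0691), within a range of 0.00321 to 0.952 over the alternatives.

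Transcription factors and stress sensors made as membrane proteins rose in 12 of 15 cases (12 adjusted over the list alone), with a median of 1.10. EIF2AK3, the ER stress kinase PERK, rose by 2.46 and NOTCH2 by 2.28, while ERN1, the stress sensor IRE1, differed by 0.07 (adjusted p 0.659) and CREB3 by 0.02 (adjusted p 0.864). The ZNF zinc finger genes, whose products are soluble, fell in 102 and rose in 5 of 231 cases (102 and 5 adjusted over the list alone; 3 rose without membrane-bound replicate 1, free replicate 2 or free replicate 3), with a median of -0.23. After centring on soluble-protein lists 169 rose and 2 fell, with a median of 0.44, and the list did not pass camera (adjusted p 0.113, the highest of a range from 0.000681 over the alternatives). The lists differed by 1.33 in their medians (adjusted p 1.75e-24; adjusted p = 0.000643 with an estimated correlation). ZNF395 and ZNF330 fell by 1.02 and 0.99, ZNF654 rose by 0.63, and ZNF91 differed by 0.43 but did not pass without free replicate 3 (0.31) or membrane-bound replicate 1 (0.39). Soluble factors of the unfolded protein response fell in 10 and rose in 0 of 12 cases (10 and 0 adjusted over the list alone), with a median of -0.44 that was 0.23 after that centring; ASNS fell by 0.77 and CEBPG by 0.75. XBP1, whose unspliced mRNA encodes a membrane-associated peptide, rose by 0.89 ± 0.12. Camera gave adjusted p-values of 2.11e-08 for the membrane-anchored list, 0.00155 for ZNF genes and 0.00572 for the soluble response factors (adjusted p = 0.0546, 0.0758 and 0.263 with an estimated correlation).

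Tail-anchored proteins reach membranes only after their translation, and of 49 such genes 40 fell and 0 rose (42 and 1 adjusted over the list alone), with a median of -0.47 that was 0.21 after centring on soluble-protein lists. STX7, a syntaxin of endosomes, fell by 1.03 (-0.66 on the mean of its probe sets) and UBE2J1, a ubiquitin-conjugating enzyme of the ER, by 0.92 (-0.42 without probe sets ending in _s_at or _x_at), while the anti-apoptotic BCL2 differed by 0.10 (adjusted p 0.366) and HMOX1, heme oxygenase, by 0.24 (adjusted p 0.0655). HMOX1 was called higher without membrane-bound replicate 2 (0.30, adjusted p 0.0494), without the dimmest 40% of probe sets and on the mean of probe sets (both 0.24, adjusted p 0.0441 and 0.046), and by 0.91 after that centring. The list lay 0.71 log2 units below the solute carriers, a difference of medians of -0.71 that became -1.40 and -1.96 without the dimmest 40% and 60% of probe sets (adjusted p 1.3e-29; adjusted p = 0.00102 with an estimated correlation). Against all other genes camera gave an adjusted p of 9.74e-07 (adjusted p = 0.0758 with an estimated correlation). The signal recognition particle and cytosolic targeting factors fell in 8 and rose in 0 of 10 cases (8 and 0 adjusted over the list alone), with a median of -0.39 that was 0.28 after that centring and an adjusted p of 0.0335 (adjusted p = 0.447 with an estimated correlation). SRP54, the subunit that binds signal sequences, fell by 0.90. That list did not pass without free replicate 1 (6 fell, adjusted p 0.0543), membrane-bound replicate 1 (6 fell, 0.0545) or membrane-bound replicate 2 (5 fell, 0.0543), within a range of 0.0123 to 0.236 over the alternatives.

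Genes of membrane traffic went both ways. Coats and tethers fell in 68 and rose in 15 of 105 cases (69 and 16 adjusted over the list alone), with a median of -0.44 that was 0.23 after centring on soluble-protein lists and an adjusted p of 0.0022 (adjusted p = 0.447 with an estimated correlation). SEC24C, a cargo subunit of the COPII coat, fell by 1.02 and VPS37C by 0.85. SAR1A and SAR1B, the near-identical GTPases that start COPII coats, rose by 2.56 ± 0.10 and 2.54 ± 0.12. RAB GTPases fell in 20 and rose in 7 of 42 cases (21 and 7 adjusted over the list alone; 4 rose without free replicate 2), and with centring on soluble-protein lists 26 rose and 1 fell. RAB21 and RAB31 fell by 0.92 and 0.86, and RAB8B and RAB4A rose by 0.65 and 0.53. Camera gave an adjusted p of 0.101 for the RAB list (adjusted p = 0.479 with an estimated correlation).

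The cytosolic and nuclear machinery lay lower in the membrane-bound fraction. Splicing factors and hnRNP proteins fell in 59 and rose in 1 of 66 cases, with a median of -0.67, and the gene that rose was SRSF11 (0.46), whose remaining probe set gave -0.14 (adjusted p 0.273) without sets ending in _s_at or _x_at and whose mean over probe sets, 0.13, did not pass. Proteasome subunits fell in 33 and rose in 2 of 39 cases, with a median of -0.64; PSMC3 fell by 0.98 and PSMD4 by 0.94 (-0.20, adjusted p 0.134, without such sets), while PSMG1, an assembly chaperone, rose by 0.71 and PSMD3 by 0.63. Genes of DNA replication and the cell cycle fell in 39 and rose in 4 of 48 cases, with a median of -0.55; MCM4 and MCM7 fell by 1.14 and 1.02, while FEN1, a flap endonuclease, rose by 0.91. Cytoskeleton and keratin genes fell in 37 and rose in 3 of 57 cases, with a median of -0.39 (0.28 after centring on soluble-protein lists). Among them TUBB3 fell by 0.90 and ARPC4 rose by 0.84, but had a difference of 0.21 (adjusted p 0.0673) without probe sets ending in _s_at or _x_at. The medians of the first 3 of these lists lie near 0 by construction when arrays are centred on soluble-protein lists, to which they belong. Adjusted over the list alone, 59, 34, 39 and 37 fell and 1, 2, 5 and 3 rose. Camera gave adjusted p-values of 1.35e-10, 5.21e-06, 5.21e-06 and 0.000247 for the 4 lists in this order, and adjusted p = 0.305, 0.33, 0.329 and 0.3 with an estimated correlation.

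Cytosolic chaperones and the chaperonin fell in 31 of 34 cases (31 adjusted over the list alone), with a median of -0.72; this list too is part of the soluble-protein centring, which brings it near 0 by construction. CCT8, a chaperonin subunit, fell by 1.00 and HSPA4 by 0.93, and without probe sets ending in _s_at or _x_at these were -0.03 (adjusted p 0.878) and -0.49. The 2 that rose were HSP90AA1 by 0.82 ± 0.096 and HSP90AB1 by 0.70 ± 0.086, the inducible and constitutive forms of cytosolic HSP90. The ER folding list lay 2.66 log2 units above the cytosolic chaperones in its median (adjusted p 3.38e-32; adjusted p = 0.000643 with an estimated correlation). Against all other genes camera gave the cytosolic chaperones an adjusted p of 8.13e-07 (adjusted p = 0.305 with an estimated correlation).

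Glycolytic and pentose phosphate enzymes fell in 16 and rose in 3 of 23 cases (16 and 3 adjusted over the list alone), with a median of -0.43 that was 0.24 after centring on soluble-protein lists. ALDOC fell by 0.96 and RPE by 0.80, whereas TKT (transketolase) and PFKP (platelet phosphofructokinase) rose by 1.28 and 1.27. Translation initiation and elongation factors fell in 40 and rose in 2 of 51 cases (40 and 2 adjusted over the list alone), with a median of -0.53 that was 0.15 after that centring. EIF4H and ETF1 fell by 0.92 and 0.88, and the 2 that rose were the membrane-spanning EIF2AK3 and EIF2AK1 (0.91), a soluble kinase of the same target. Aminoacyl-tRNA synthetases fell in 12 and rose in 2 of 17 cases (13 and 2 adjusted over the list alone), with a median of -0.34 that was 0.33 after that centring and -0.57 without probe sets ending in _s_at or _x_at; HARS1 and WARS1 fell by 0.93 and 0.90, and EPRS1 and AIMP1 rose by 1.25 and 0.71. Camera gave adjusted p-values of 0.0291, 9.49e-06 and 0.0288 for the 3 lists, and adjusted p = 0.447, 0.324 and 0.543 with an estimated correlation. The synthetases did not pass without membrane-bound replicate 1 (adjusted p 0.0545), within a range of 0.00449 to 0.243 over the alternatives.

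Mitochondrial proteins encoded in the nucleus lay mostly lower. Mitochondrial ribosomal proteins fell in 40 and rose in 3 of 51 cases (44 and 3 adjusted over the list alone), with a median of -0.57 that was 0.10 after centring on soluble-protein lists. MRPS11 and MRPL49 fell by 0.93 (-0.49 on the mean of its probe sets) and 0.81, and MRPS28 and MRPS22 rose by 1.61 and 1.05. Subunits of oxidative phosphorylation fell in 46 and rose in 15 of 68 cases (46 and 15 adjusted over the list alone), with a median of -0.45 that was 0.22 after that centring. NDUFV1 and NDUFS6 fell by 1.00 and 0.92, and NDUFA13 and NDUFA9, all 4 in respiratory complex I, rose by 1.36 and 1.31. The adjusted p by camera was 1.69e-05 and 0.031, and adjusted p = 0.375 and 0.628 with an estimated correlation. The oxidative phosphorylation list did not pass without free replicate 1 (adjusted p 0.0558), membrane-bound replicate 1 (0.0677) or membrane-bound replicate 2 (0.0543), within a range of 0.00616 to 0.332 over the alternatives.

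Cytosolic ribosomal proteins moved little: 15 fell and 1 rose of 56 (13 and 1 adjusted over the list alone), and with centring on soluble-protein lists 51 rose and 0 fell. Their median was -0.11, with an adjusted p of 0.288 by camera (adjusted p = 0.728 with an estimated correlation). RPL39L fell by 0.68, RPL36 by 0.57 and RPL18 rose by 0.38 (0.21 on the mean of its probe sets). Histones fell in 14 and rose in 7 of 46 cases (14 and 7 adjusted over the list alone), and with that centring 37 rose and 1 fell. H1-10 fell by 1.00 and H4C8 by 0.88, while H2AC16 and H2AC25 rose by 0.64 (0.19 with a pseudocount of 64) and 0.63. The histones' median of -0.05 (-0.36 without the dimmest 60% of probe sets) and mean of -0.08 lay below 0 while camera ranked them slightly up, with an adjusted p of 0.996 (adjusted p = 0.995 with an estimated correlation). Of 3 nuclear-retained noncoding RNAs, too few for a list test, TUG1 rose by 1.02 (1 also adjusted over the list alone), and MEG3 differed by 0.03 (adjusted p 0.857) and KCNQ1OT1 by -0.06 (adjusted p 0.671), the last at 0.61 after that centring. MEG3 and KCNQ1OT1 were dim, at 6.44 and 4.31 in free polysomes, below the median of all probe sets (7.05), whereas TUG1 stood at 10.52.

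Genes that mark luminal breast cells or respond to estrogen divided evenly, with 11 higher and 12 lower of 29 (11 and 13 adjusted over the list alone); with centring on soluble-protein lists 20 rose and 0 fell. AGR2, a disulfide isomerase of the secretory pathway, rose by 2.23, SLC7A5 by 2.21, and TFF3 and TFF1, secreted trefoil peptides, by 1.77 and 0.79. Outside the list, benchmark genes MUC1, a membrane mucin, and CD24, a surface glycoprotein held by a GPI anchor, rose by 2.11 and 0.56. ESR1, the estrogen receptor, fell by 0.90 (-0.30 on the mean of its probe sets) and CCND1, cyclin D1, by 0.93; centred on soluble-protein lists they did not pass (-0.23, adjusted p 0.0626, and -0.26, adjusted p 0.0758). GATA3 differed by -0.01 (adjusted p 0.942) on its brightest probe set, while without sets ending in _s_at or _x_at another called it lower (-0.53, adjusted p 0.000402). PGR, the progesterone receptor, differed by -0.24 (adjusted p 0.0757) and by -0.31 without free replicate 2, where it passed. Its probe set was dim, at 5.38 in free and 5.14 in membrane-bound polysomes. Centred on soluble-protein lists GATA3 and PGR stood at 0.66 and 0.43. The median of -0.20 and the mean of 0.35 had opposite signs, and camera gave an adjusted p of 0.112 (adjusted p = 0.607 with an estimated correlation), which became 0.0441 without free replicate 1, 0.0432 without the dimmest 60% of probe sets and 0.0484 without sets ending in _s_at or _x_at, within a range of 0.0432 to 0.442 over the alternatives. Among abundant reference genes KRT8 fell by 0.56 and TUBA1B by 0.37, and GAPDH (-0.19, adjusted p 0.0893), ACTB (-0.13, adjusted p 0.325), KRT18 (-0.09, adjusted p 0.451) and EEF1A1 (-0.08, adjusted p 0.52) did not pass; centred on soluble-protein lists these 6 stood at 0.11, 0.30, 0.49, 0.54, 0.58 and 0.60.

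**Figure D2:**
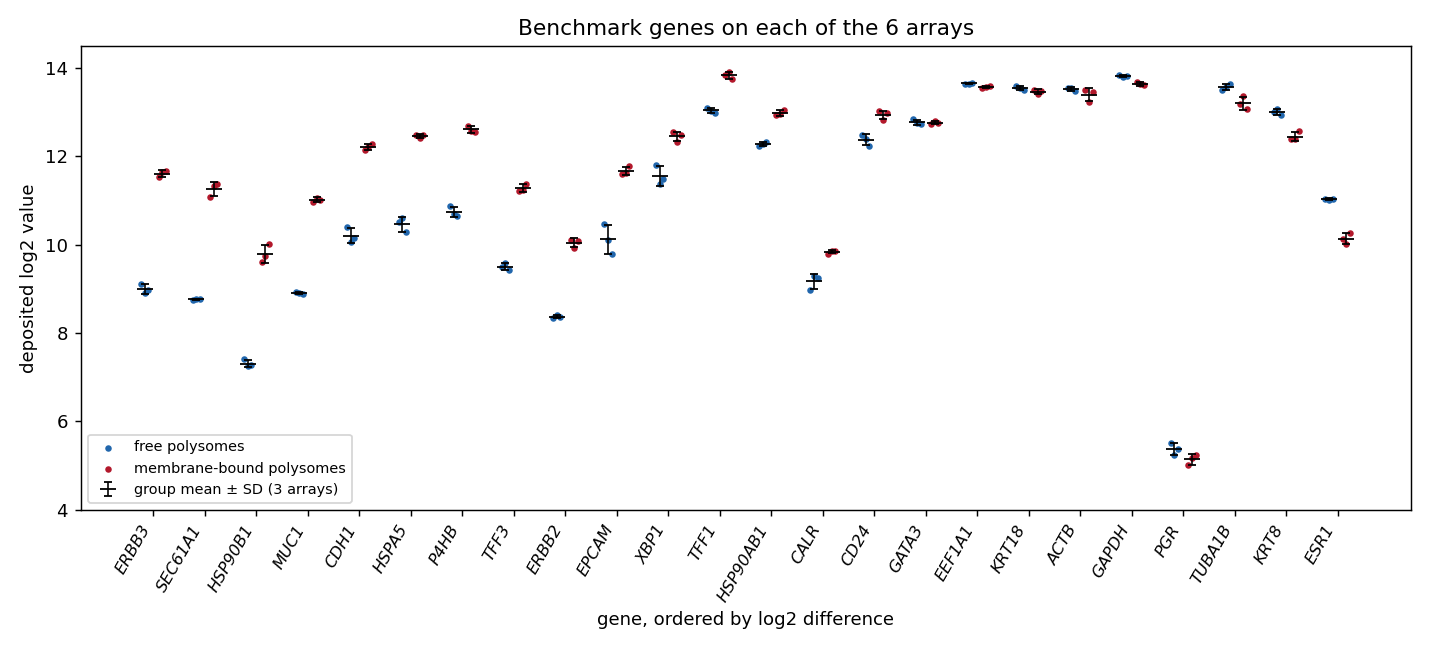
Deposited log2 values (vertical axis) of 24 benchmark genes, ordered by the difference between fractions, on each of the 3 free (blue) and 3 membrane-bound (red) arrays, with group means and SD as black bars. ERBB3, SEC61A1 and HSP90B1 lie 2.61, 2.50 and 2.48 log2 units higher in the membrane-bound fraction, and ESR1 lies lower by a difference of -0.90 as deposited.

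Of 35 lists tested with the preset correlation 29 passed, 13 up and 16 down, and 21 of the 29 also passed in all 19 alternatives with that setting. Among the 19, the intensity trend does not enter camera and could not change this count. Without the dimmest 60% of probe sets, soluble sterol enzymes, soluble stress response factors, targeting factors, coats and tethers, glycolysis, tRNA synthetases and oxidative phosphorylation did not pass. Their medians then lay between -0.55 and -0.34, no nearer 0 than with all probe sets. The median of all genes was then -0.37, against -0.07 with all probe sets, so camera compared these lists with genes that also lay lower. With centring on soluble-protein lists ZNF genes, targeting factors and glycolysis did not pass. With an estimated correlation 0 passed in camera, the lowest adjusted p being 0.0546 and 12 having an unadjusted p under 0.05, while fry, which does not compare a list with other genes, called 33 and the 5 differences between list pairs passed both ways.

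**Figure D3:**
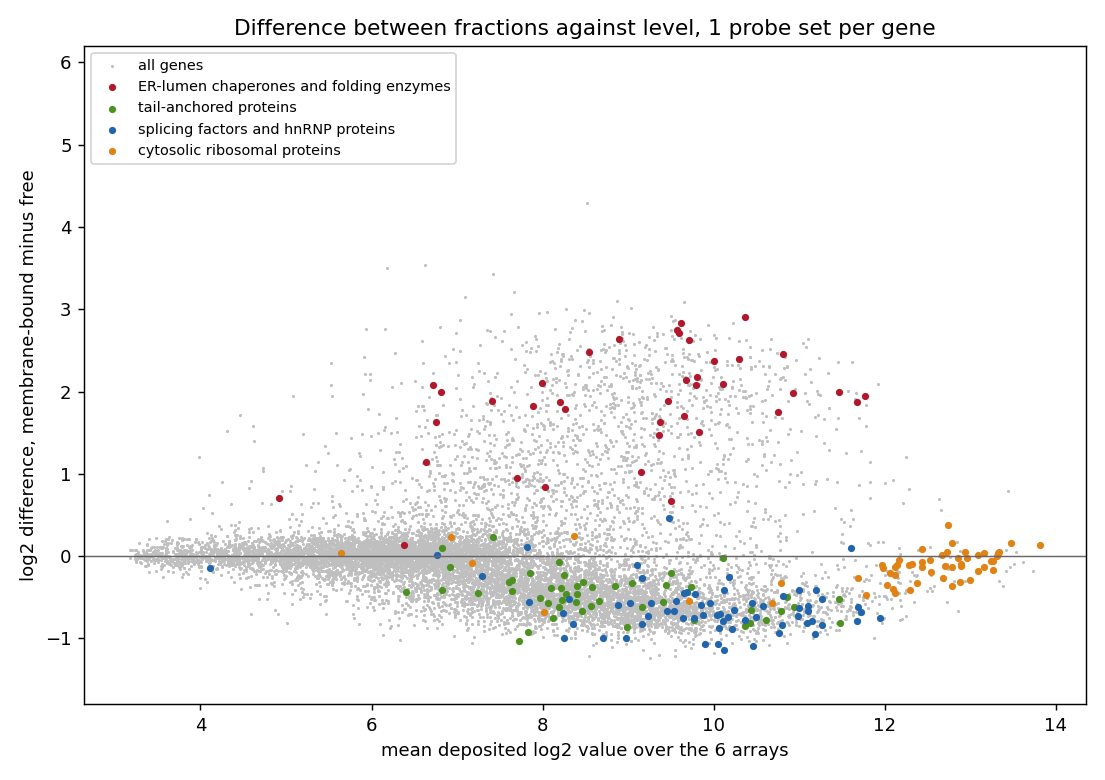
Log2 difference between membrane-bound and free polysomes (vertical axis) against the mean deposited log2 value over the 6 arrays (horizontal axis) for 11963 genes in grey, with 4 gene lists in colour. ER-lumen chaperones have a median of 1.94, tail-anchored proteins and splicing factors medians of -0.47 and -0.67 as deposited (the first at 0.21 and the second near 0 by construction when centred on soluble-protein lists), and ribosomal proteins crowd at the bright end.

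Large increases were rare among the brightest probe sets. The 90th percentile of the log2 difference was 1.97 for probe sets with a mean level of 10 to 11, 1.68 at 11 to 12, 0.10 at 12 to 13 and 0.11 at 13 and over. Among the dimmest, under 5, it was 0.16. TFF1 was among the brightest, with 13.04 in free and 13.83 in membrane-bound polysomes. The probe sets called at least 2-fold higher in the membrane-bound fraction made up 6.14% ± 0.013 of the summed linear signal on free arrays and 22.8% ± 0.38 on membrane-bound arrays (SD, n = 3 each), a comparison of probe sets picked for that difference.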

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

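The alternative without free replicate 1 and membrane-bound replicate 3 was chosen after seeing the data. All 1087 genes at least 2-fold higher in the membrane-bound fraction were still called higher in each alternative that measured them, except without probe sets ending in _s_at or _x_at (710 of 749). The 5 differences between list pairs passed in all 19 alternatives in which they were run. Among these the intensity trend does not enter camera and repeated the main p-values. Median centring and centring on soluble-protein lists leave a difference of medians unchanged by construction. Leaving out single arrays gave 9364 to 10725 probe sets, 1904 to 2036 at 2-fold, 5580 to 6341 genes and 25 to 30 lists, and the 4 arrays gave 10983, 1980, 6477 and 30. Against a 1.2-fold margin 6436 probe sets and 3888 genes passed, by construction of a stricter test, and without sets ending in _s_at or _x_at 3709 genes passed among fewer genes tested. In camera with an estimated correlation 0 of 35 lists passed, with 12 at an unadjusted p under 0.05 and 33 lists called by fry. Of the 29 lists, 8 were lost in at least 1 alternative that kept the preset correlation: soluble sterol enzymes (highest adjusted p 0.952), oxidative phosphorylation (0.332), glycolysis (0.271), tRNA synthetases (0.243), the signal recognition particle (0.236), ZNF genes (0.113), soluble stress factors (0.0994) and trafficking coats (0.0951). The cause was not tested, but without the dimmest 60% of probe sets the median of all genes itself moved from -0.07 to -0.37. On that setting a list median near -0.37 does not set a list apart from other genes. Dim probe sets limit what can be seen: under a level of 5 the 10th and 90th percentiles of the difference were -0.15 and 0.16.

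Same-numbered arrays did not deviate together (r of -0.29, 0.15 and -0.35 over genes), and no array's deviations correlated best with those of its own number. Free replicate 1 and membrane-bound replicate 3 deviated together (r of 0.45), which can hide weaker shared deviations. With few arrays, whether the numbers pair the samples therefore stays open. With the replicate block 9910 probe sets and 5868 genes passed, along with 29 lists.

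Centring on soluble-protein lists gave 17133 probe sets, 16888 higher and 245 lower, and 3064 at 2-fold, all higher, since it raised the median of all genes from -0.07 to 0.60. Of 6200 genes called, 2068 kept their call and 1090 were called the opposite way; 98.7% of the genes called were higher, against 31.5%. That shift turned these log2 differences from below to above 0: SERP1 0.15, SEC61B 0.18, SRP19 0.048, SGTA 0.62, SRP72 0.65, FLT4 0.53, ROR1 0.56, ITGAE 0.091, PCDH8 0.46, FGF13 0.071, FGF12 0.33, LTBP4 0.27, SERPINB5 0.15, IDS 0.65, ST8SIA5 0.47, PIGA 0.16, SLC27A5 0.17, SLC27A6 0.41, TRPM6 0.48, ABCC9 0.49, TMEM243 0.14, TMEM11 0.24, LSS 0.39, EIF2AK2 0.49, PPP1R15A 0.60, RPL36 0.098, KRT14 0.37, CD14 0.55, KCNQ1OT1 0.61, PGR 0.43, GATA3 0.66, KRT8 0.11, KRT18 0.58, GAPDH 0.49, ACTB 0.54, TUBA1B 0.30 and EEF1A1 0.60. Without sets ending in _s_at or _x_at, ERBB3 stood at -0.12 and SRSF11 at -0.14, measured by other probe sets. Calls were also lost there for HNRNPM (-0.08), PSMD4 (-0.20), CCT8 (-0.03), ARPC4 (0.21) and COL3A1 (0.061), and GATA3 was called at -0.53. GAPDH was called lower, between -0.18 and -0.21, with a pseudocount of 64, without the dimmest 60%, with median centring, quantile normalization within groups or an intensity trend, and over the mean of its probe sets. With that list centring FKBP10, CTSZ, ERN1, CREB3, BCL2, HMOX1 and MEG3 were called higher, at 0.70 to 0.91. Against the 1.2-fold margin KRT14, LSS, MVK, PIGA, RAB4A, RPL18, SLC27A6, SRSF11, TMEM11, TUBA1B and ZNF91 did not pass. The KRT14 call was lost with the replicate block and a pseudocount of 64, and that of PIGA with the pseudocount. SLC27A6 (-0.26 on all arrays) lost its call with the replicate block and without free replicate 1 or 2 or membrane-bound replicate 1 or 2. The histones (median -0.046) were called lower by fry, whereas camera placed them slightly up.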

Other observations

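The tests of intensity compression and of mitochondria in the membrane fraction, and the 10 gene lists used here, were chosen only after the main results were seen; p-values of these lists were adjusted over the 10. In the membrane-bound fraction 17 of 17 enzymes of sphingolipid synthesis and fatty acid elongation rose, with a median of 2.23 log2 units (camera, adjusted p 9.99e-16, and adjusted p = 0.0292 with an estimated correlation). CERS6, a ceramide synthase, rose by 2.78 ± 0.084 (SE, n = 3 per group), HACD3, a dehydratase of the elongation cycle, by 2.77, and SPTLC1, of the enzyme that starts sphingolipids, by 2.40. All 6 TMED cargo receptors measured rose, between 1.62 (TMED1) and 2.41 (TMED9), with an adjusted p of 3.33e-07 (adjusted p = 0.028 with an estimated correlation). Class I histocompatibility chains and their loading factors rose in 12 of 13 cases, with B2M, the shared light chain, at 2.03 and TAPBP, the tapasin chaperone, at 1.93 (adjusted p 1.65e-10; adjusted p = 0.028 with an estimated correlation).

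Members of other complexes went different ways on the deposited scale, less so with arrays centred on soluble-protein lists. In the ER membrane complex, an insertase, EMC7, EMC3 and EMC1 rose by 2.91, 2.65 and 2.38, and EMC2, a subunit in the cytosol, fell by 0.58 (a difference of 0.089 with that centring). The other 4 of 8 did not pass, among them the cytosolic EMC8 (-0.18, adjusted p 0.175) and EMC9 (0.10, adjusted p 0.413) and the membrane-spanning EMC6 (-0.05, adjusted p 0.72). With that centring 7 of the 8 rose and 0 fell, with EMC8, EMC9 and EMC6 at 0.49, 0.77 and 0.62. The list had an adjusted p of 0.0207 (adjusted p = 0.273 with an estimated correlation). Of 14 peroxins and peroxisomal transporters 7 rose and 5 fell (adjusted p 0.061; adjusted p = 0.368 with an estimated correlation), and with that centring 10 rose and 0 fell. ABCD3 and PEX3, membrane proteins of peroxisomes, rose by 2.47 and 2.02, while PEX19, the soluble receptor for such proteins, fell by 0.61, or stood at 0.061 with that centring. Not all membrane proteins of this list rose. PEX2 and PEX26 fell by 0.43 and 0.58, or stood at 0.24 and 0.091 with that centring, and the transporter ABCD2 differed by -0.04 (adjusted p 0.804). Among 11 COPII and ARF-family GTPases, which have no membrane span, 4 rose and 3 fell (adjusted p 0.061; adjusted p = 0.368 with an estimated correlation), and with that centring 8 rose and 1 fell. The 4 were SAR1A (2.56), SAR1B (2.54), ARF5 (1.80) and ARL1 (1.35), and the 3 were ARL3 (-0.98), ARF6 (-0.52) and ARL2 (-0.51), of which ARF6 and ARL2 stood at 0.15 and 0.16 with that centring.

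A hypothesis was that subunits of a complex part by whether they are inserted in a membrane, and it was tested on 2 complexes. In the V-ATPase, the proton pump of lysosomes, 8 of 9 membrane-sector and accessory genes rose and 8 of 9 soluble-sector genes fell, with list medians of 1.68 and -0.47 that became 2.35 and 0.20 after centring on soluble-protein lists. The difference of medians was 2.15 (camera between the lists, p 1.17e-05; p = 0.00576 with an estimated correlation). On the deposited scale the exception in the membrane sector was ATP6V0D1 (-0.31), a subunit without a membrane span, against 2.69 for ATP6AP2 and 2.38 for ATP6V0B; with that centring ATP6V0D1 was called higher (0.36) and all 9 rose. At the nuclear envelope, 8 of 11 membrane proteins rose and 1 fell, among them LBR (2.39) and NDC1 (2.39), while 18 of 24 soluble nucleoporins fell and 2 rose, with NUP62 at -0.88; after that centring 12 of the 24 rose and 0 fell. Those medians differed by 2.35 (p 1.31e-07; p = 0.00857 with an estimated correlation). Both values went the way the hypothesis predicted, and a difference between list medians is the same under any centring of whole arrays. Both complexes were chosen after the main lists had shown this pattern, so the p-values are not independent support. No such test was run on the ER membrane complex or the peroxins, where the membrane proteins EMC6, PEX2 and PEX26 did not rise on the deposited scale. SYNE2 (-0.40) and SYNE1 (-0.02, adjusted p 0.925), giant proteins with a C-terminal anchor, and SUN1, whose probe sets were called at both 2.08 and -0.40, were the exceptions or split cases among the envelope proteins, along with POM121 (0.12, adjusted p 0.332). With that centring 11 of 11 envelope proteins rose on their main probe sets, SYNE2, SYNE1 and POM121 by 0.27, 0.66 and 0.80.

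On the deposited scale ribosomal protein mRNAs lay less far down than other mRNAs of soluble proteins: at a level of 12 or more, 47 ribosomal genes had a median of -0.11 against -0.37 for 37 others. Compression of bright signals was tested by matching 45 pairs on their level in free polysomes within 0.2 log2 units. The ribosomal member still lay higher by a median of 0.28 (permutation test within pairs, 100000 resamples, p 2e-05), which argues against compression as the whole cause, although ribosomal members were also brighter by a median of 0.14. P-values of this permutation test measure the spread between gene pairs, not between samples, and treat genes that can vary together as independent. Probe sets shared with ribosomal pseudogenes could not be told apart as a cause: the 13 genes on sets without _s_at or _x_at endings gave a gap of 0.21 (p 0.0741), and few pairs keep this open. A difference in where these mRNAs are translated stays open and was not tested.

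Some mRNAs of mitochondrial proteins were higher in the membrane-bound fraction on the deposited scale. They were 24 of the 147 members of the 3 mitochondrial lists, which also held the peroxisomal carrier SLC25A17, or 16.3%, against 98 that were lower. Over all genes 1952 of 11963 were higher, a similar share, so the lists held no excess of higher members. With arrays centred on soluble-protein lists 8765 of all genes were higher. Mitochondria carried into the fraction with the mRNAs of all their proteins would have raised most members, and the share of 16.3% argues against that, less firmly with arrays centred on soluble-protein lists, where 46.9% were higher and 5 members were still lower. Probe sets that read another transcript cannot be told apart as a source, since only 2 other probe sets of these genes lay above the array median; both, or 100%, were called higher, COX4I1 at 0.73 and SLC25A14 at 0.64. No biological explanation was tested.

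With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split was the only 1 of 10 to give 10501 probe sets, 1937 at 2-fold or 6200 genes, and the highest of the others was 0 for each. Each other split mixed the fractions in both groups, so the fraction difference widened the spread within groups and left little to call. Those counts of 0 therefore say nothing about chance. For gene lists with the preset correlation, 3 of 10 splits gave 29 or more, and the highest other was 30, so that count does not set the real split apart. The other splits still carried part of the fraction difference, so they cannot show what the list test gives without one. Of the 4 splits that put free replicate 1 with membrane-bound replicate 3, 2 gave 30 lists and the others 12 and 11, the lowest of all; without both arrays 30 lists passed for the real fractions. Probe sets of 1 gene were called in opposite directions for 23 genes, among them MARCHF6 (2.83 and -0.24), SLC35E1 (2.36 and -0.24), ZMYM6 (1.27 and -0.47) and ESR1 (0.29 and -0.90). Unnamed probe sets at least 2-fold different numbered 97 higher and 8 lower.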
